A study of Mus musculus with 12 samples.

How the data were processed

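Gene expression was measured on 12 Affymetrix mouse genome arrays, 3 for each of 4 groups. The groups were wild-type LSK cells, FoxO-deficient LSK cells, wild-type myeloid progenitors and FoxO-deficient myeloid progenitors. Per the labels' protocols, cells were sorted from bone marrow of pooled mice carrying floxed alleles of Foxo1, Foxo3 and Foxo4, with the Mx-Cre transgene for the deficient groups and without it for the wild-type groups. Per the same protocols, RNA was amplified and biotin-labelled as cDNA with the NuGEN Ovation system in triplicate. The labels do not say whether the 3 arrays of a group came from separate pools of mice, so p-values measure only the spread between these arrays, which may be technical. Arrays are named by their group and the number in their title, from 1 to 12. No number is shared between groups, so no arrays were paired.

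The deposited values are intensities on a linear scale, 1 summary value for each of 45101 probe sets on each array. The software with which the authors summarised probes to probe sets is not given in the sources used here. No value was negative, and the array medians ran from 8 to 13.5, so the deposited intensity values had not been brought to a common distribution. At most 1.55% of the probe sets had the same value on any pair of arrays, so no array was a copy of another.

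From these intensities, log2(intensity + 0.6) was computed, the offset being the 10th percentile of all values, and the arrays were quantile normalized. Fold changes are on this scale. The offset lowers the change of dim genes, but it lies under the background limits given below, so values near background can also overstate it. Of the probe sets, 64 were manufacturer's controls and stayed out of the tests. In the platform annotation used here, 34945 of the others carried 1 gene symbol, 932 carried several and 9160 carried none. Genes were named only from probe sets with 1 symbol, and 34741 of these symbols were brought up to date through the gene identifier in a RefSeq gene table of assembly GRCm38.p6. That table also gave the start positions by which genes were ordered along chromosomes, with only tested genes counted in that order. A probe set was kept if it lay above the 40th percentile of its array on at least 3 arrays. Each gene was represented by its kept probe set with the highest mean over the 12 arrays, which left 13732 genes. For genes given as called, other kept probe sets of opposite sign are mentioned.

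A background limit was set on each array as the highest normalized intensity among 27 control probe sets for bacterial transcripts that gave little signal; it lay between 5.14 and 13 on the 12 arrays. Where the dimmer group of a gene did not exceed this limit on any of its 3 arrays, the change is given as "at least" a fold. This bound sets the brighter group's mean against the mean of the limits, or of the gene's own values where higher. No fold is given where the dimmer group exceeded the limit on only 1 of 3 arrays, where the brighter group was also at or below the limit on all 3 arrays, or where the bound fell under 1. Group intensities are the antilog of the mean log2 value of 3 arrays. The number of arrays limits the precision of every value.

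A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which leaves 8 residual degrees of freedom per gene. The 4 contrasts were FoxO-deficient against wild-type LSK cells, FoxO-deficient against wild-type myeloid progenitors, the difference between these effects, and wild-type myeloid progenitors against wild-type LSK cells. Only the deficient groups carried Mx-Cre, so what is called a FoxO effect includes any effect of that transgene. All tests were two-sided, with Benjamini-Hochberg adjustment over the 13732 genes, and a gene was called at an adjusted p under 0.05. Errors of log2 changes are standard errors of this fit, with 3 arrays per group.

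Lists of genes were tested with camera from limma, with a preset correlation between genes of 0.01 and adjustment over the 32 lists within a contrast; the alternatives were an estimated correlation and fry. The 31 lists were antioxidant enzymes, glutathione metabolism, ROS-producing enzymes, FoxO targets, HSC genes, granulocyte-monocyte progenitor genes, late neutrophil granule genes, monocyte and macrophage genes, eosinophil, basophil and mast cell genes, erythroid genes, megakaryocyte genes, lymphoid-primed and lymphoid progenitor genes, mature B cell genes, T and NK cell genes, stromal and endothelial genes, cell cycle S phase, cell cycle G2 and M phase, cell cycle inhibitors, apoptosis regulators, p53 targets, interferon response, immediate-early and dissociation genes, glycolysis, oxidative phosphorylation, hypoxia response, autophagy and lysosome, ribosomal proteins, cholesterol synthesis, unfolded protein response, insulin and PI3K signalling, and the Wnt pathway. The union of the first 3, called ROS metabolism, was tested as a further list. Some genes stand on more than 1 list.

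The genes named in the text follow a rule. It takes every probe set of Foxo1, Foxo3, Foxo4 and Foxo6, and the 8 genes with the largest rise and the 8 with the largest fall for FoxO deficiency in each cell type. For the difference of the effects and for the cell type comparison it takes 5 and 5. Genes of this part had to be called, and clone names were passed over. Except for the difference of the effects, they also had to show no overlap between the arrays of the groups compared. From each list described it takes up to 4 members with the smallest adjusted p, 8 for ROS metabolism, and all called members where there are 5 or fewer. Genes named outside this rule are said to be. The groups, contrasts, offset, filter, lists, naming rule and most alternatives were fixed before the data were examined.

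The alternatives were the deposited values without further normalization, median centring, an offset of 0.25 or 4 times the main one, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, every kept probe set, a fit of only the groups compared, a variance trend, array weights, a 2-fold minimum, and leaving out each array in turn. An offset of 32, alone and without wild-type LSK array 2, was added after seeing the data, as was the estimated correlation without that array.

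The fits were tested on simulated data for the 13732 genes, drawn from the measured means and residual spreads, with 200 genes changed per contrast, 50 at each of 4 sizes. A first version with 1 draw gave shares that moved with the order of the genes, so 100 draws were made and their mean is given. At an 8-fold change, 72.8% of changed genes were recovered for LSK cells, 72.8% for myeloid progenitors, 71.3% for the cell type comparison and 54.4% for the difference of the FoxO effects. At a 2-fold change the shares were 19.2%, 20.5%, 19.7% and 4.92%, so most 2-fold changes are beyond the reach of 3 arrays per group with this spread. That spread includes wild-type LSK array 2, and recovery was not simulated without it. Without that array the median standard error fell from 0.357 to 0.238 in LSK cells and 0.213 in myeloid progenitors. Of the calls in these simulations, between 5.44% and 6.39% were false. A simulated list of 17 genes shifted up by 0.5 in LSK cells was recovered by camera in 85 of 100 draws, and other lists were called in 6 of the 100. Genes were drawn independently of each other, so these list shares do not hold where the genes of a list are correlated. In splits of the real arrays that mixed the wild-type cell types, up to 10 lists were called.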

Results

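FoxO transcription factors act downstream of insulin and growth factor signalling. The labels state the study's question as how deficiency of FoxO1, FoxO3 and FoxO4 affects the expression of genes of reactive oxygen species (ROS) metabolism in hematopoietic stem cells (HSCs) and myeloid progenitors. Expression was measured on 12 arrays, 3 each of wild-type and FoxO-deficient LSK cells and of wild-type and FoxO-deficient myeloid progenitors. LSK cells are the lineage-negative bone marrow cells with Sca-1 and Kit on their surface, a fraction that holds the HSCs, and myeloid progenitors are more restricted cells. The mean deposited intensity per array ran from 119 to 190.2 and the median from 8 to 13.5.

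Wild-type LSK array 2 stood apart in RNA quality. Its Gapdh control probe sets read 3165 at the 3′ end and 9.2 at the 5′ end of the transcript, and those of Actb read 694 and 4.8. On the other 11 arrays the 3′ over 5′ ratio lay between 1.77 and 2.37 for Gapdh and between 2.74 and 3.36 for Actb. Across probe sets, the log2 values of this array correlated with those of the other arrays of its group at r = 0.867 and 0.872, and the other pairs within groups lay between 0.916 and 0.935. These correlations are across genes, which are not independent replicates. The array stayed in the fits, and the counts below are also given without it.

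**Figure D1:**
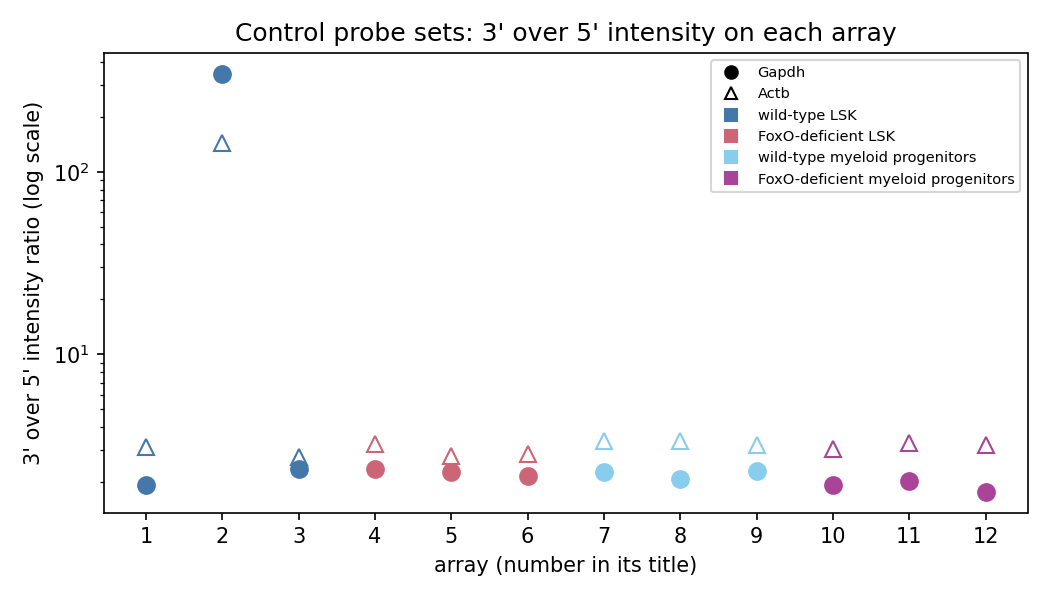
Ratio of 3′ to 5′ intensity (log axis) of the Gapdh (circles) and Actb (triangles) control probe sets on each of the 12 arrays, coloured by group. Array 2, of wild-type LSK cells, lies at 344 for Gapdh and 145 for Actb, and the other 11 arrays lie between 1.77 and 3.36.

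The targeted genes were examined first. Foxo4 fell from 393 to 85.8 in LSK cells (log2 change -2.20 ± 0.19, adjusted p = 0.00162) and from 329.8 to 59.9 in myeloid progenitors (log2 change -2.46 ± 0.19, adjusted p = 1.14e-04), with all 3 deficient arrays below all 3 wild-type arrays in both cell types. The other Foxo4 probe set did not pass the filter and read 3.73 and 4.01 in wild-type and deficient LSK cells and 2.29 and 1.98 in the myeloid progenitor groups. The brightest Foxo1 probe set read 104 and 27.2 in LSK cells and 23.4 and 12.5 in myeloid progenitors, and neither difference passed the test (adjusted p = 0.263 and 0.609). Its wild-type LSK arrays 1, 2 and 3 read 53.8, 265 and 79.5, so the degraded array raises the mean. The next brightest read 73.4 and 31.3, then 21.8 and 8.29, with all 3 deficient arrays below all 3 wild-type arrays in both cell types. Adjusted over all probe sets, neither of these differences passed (limma, adjusted p = 0.427 and 0.171). Of the 2 dim ones, 1 read 11.6 and 7.48, then 4.83 and 1.39, and the other, with the opposite sign, 8.80 and 13.5, then 6.88 and 15.3. Foxo3 was not lower in deficient cells, at 2421 and 2828 in LSK cells and 1860.3 and 2414 in myeloid progenitors (adjusted p = 0.561 and 0.299; 0.0378 in myeloid progenitors without wild-type LSK array 2). Its second probe set read 1769 and 2789 (820.4 on array 2), then 1455 and 2387, and its last lay near background at 7.86 and 8.58, then 4.21 and 4.03. The sources used here do not say which part of each gene was deleted, and a probe outside that part does not report the deletion. Foxo6 has no probe set paired with it alone in the annotation used here.

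**Figure D2:**
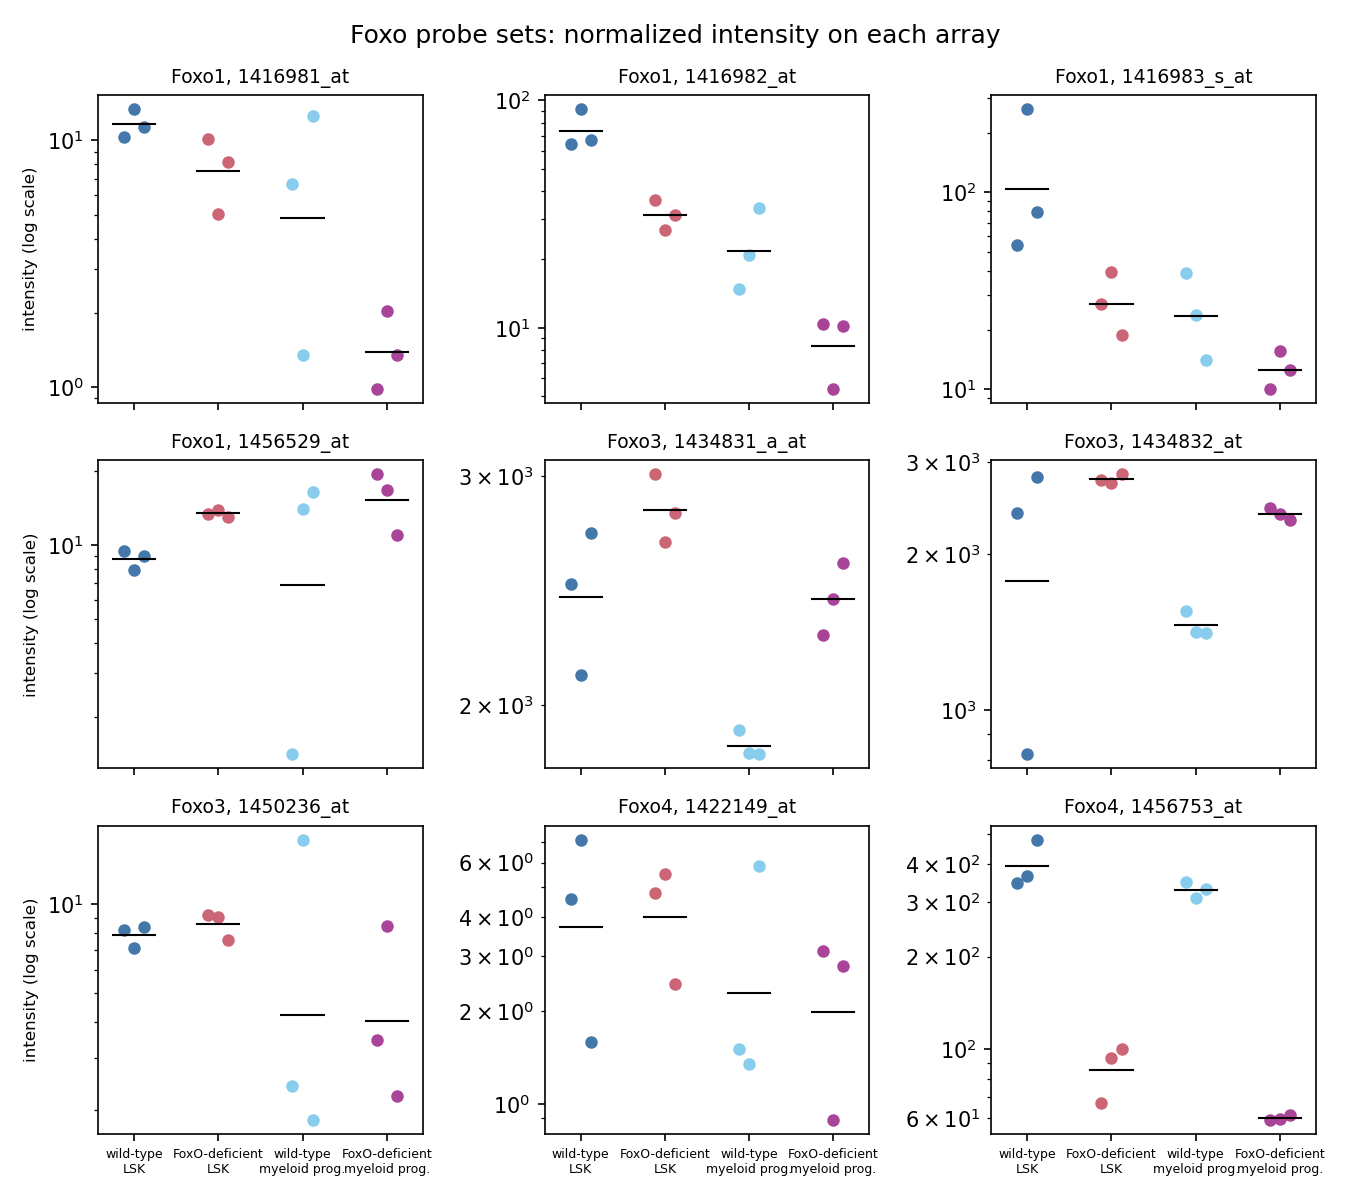
Normalized intensity (log axis) of each probe set of Foxo1, Foxo3 and Foxo4 on the 12 arrays by group, with a point per array and a line at the geometric mean of 3 arrays. The brighter Foxo4 probe set has means of 393 and 85.8 in wild-type and deficient LSK cells and 329.8 and 59.9 in the myeloid progenitor groups.

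In FoxO-deficient LSK cells, genes of eosinophils, basophils and mast cells were higher and genes of HSCs were lower than in wild-type LSK cells. The call of the HSC list, with 2 of 35 genes called, was lost with an estimated correlation (adjusted p = 0.108). Mcpt8, a basophil protease, rose from 29.3 to 149 (log2 change 2.34 ± 0.21, adjusted p = 0.00190). Tek, the angiopoietin receptor found on HSCs, fell from 466 to 191 (log2 change -1.29 ± 0.17, adjusted p = 0.0184), and Sult1a1, a sulfotransferase on the same list, fell from 51.9 to 18.7 (log2 change -1.47 ± 0.24, adjusted p = 0.0434). In all, 37 of 13732 genes were called, 17 higher and 20 lower. Without wild-type LSK array 2, 128 genes were called, 70 higher and 58 lower, with 34 in both sets.

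Among the largest rises was Igk-V21, an immunoglobulin light chain segment, from 7.65 to 429 (log2 change 5.81 ± 0.84). The probe set that the annotation pairs with the microRNA gene Mir1931 rose from 26.3 to 596 (4.50 ± 0.35). The kinase gene Sik1 rose from 34.1 to 341 (3.32 ± 0.29), and a second probe set of Sik1 changed by 0.09. Trim12a rose at least 6.63-fold and the chemokine gene Xcl1 at least 1.69-fold from levels not above background. A second probe set of Trim12a moved far less, by a log2 change of 1.21. Ppm1j, a phosphatase gene, was called at 1.32 and 8.07 and Prg3, of an eosinophil granule protein, at 1.69 and 8.31, levels near background for which no fold is given. The largest falls were Ang, a secreted ribonuclease, from 44.0 to 2.27, not above background on 2 of 3 arrays, B3galt6, a galactosyltransferase of proteoglycan synthesis, from 186 to 12.8 (-3.86 ± 0.36), the zinc finger gene Rsl1 from 127 to 10.2 (-3.63 ± 0.43), the chemokine receptor gene Ccr2 from 67.4 to 10.7 (-2.65 ± 0.21), Arsk, a sulfatase gene, from 116 to 25.3 (-2.20 ± 0.31), Gdpd3, a phosphodiesterase gene, from 2025 to 548 (-1.89 ± 0.14), and Foxo4. Igll1, part of the pre-B cell receptor, fell at least 2.29-fold, with a second probe set at 0.53. Of 3 other Ccr2 probe sets, 1 had the sign of the called one, and the others of B3galt6 and Arsk moved far less (-0.55 and -0.77, and -0.55). The adjusted p of these 16 genes lay between 9.36e-04 and 0.0434.

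Of 15 measured eosinophil, basophil and mast cell genes, 2 were called higher and 0 lower, with 7 called when adjusted over the list alone, and the list was higher (camera, adjusted p = 6.17e-07; adjusted p = 0.0103 with an estimated correlation). Fcer1a, a chain of the IgE receptor, read 4.13 and 27.4 (adjusted p = 0.0987), and Hdc, which makes histamine, 9.24 and 30.5 (adjusted p = 0.0913). Of 35 HSC genes, 2 fell and 0 rose, with 9 called when adjusted over the list alone. The list was lower, with a median log2 change of -0.59, or -0.33 without array 2 (adjusted p = 1.04e-06; adjusted p = 0.108 with an estimated correlation). Esam, an adhesion molecule of HSCs, read 124 and 43.2 and Slamf1 117 and 47.1, without passing (adjusted p = 0.165 and 0.228). The degraded array 2 is on the wild-type side of these comparisons, and without it the lists had adjusted p = 5.65e-09 and 1.28e-04, or 0.0120 and 0.135 with an estimated correlation.

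Of 26 erythroid genes, 1 fell, the carbonic anhydrase gene Car1, from 174 to 94.2 (log2 change -0.89 ± 0.14, adjusted p = 0.0457), with 3 called when adjusted over the list alone, and the list was lower (adjusted p = 0.00662; adjusted p = 0.0848 with an estimated correlation), with a median of -0.62, or -0.27 without array 2 (adjusted p = 0.0170). The granulocyte-monocyte progenitor list was higher (adjusted p = 0.0193; adjusted p = 0.0848 with an estimated correlation) with 0 of 26 genes called and 5 when adjusted over the list alone. Its members read 95.5 and 199.8 for the neutrophil elastase gene Elane, 84.7 and 241 for Cst7 and, with the opposite sign, 132 and 71.5 for the transcription factor gene Gfi1. This call was lost without wild-type LSK array 1 or 3 (adjusted p = 0.153 and 0.151). Of 16 late neutrophil granule genes, Fcnb rose from 14.7 to 69.5 (log2 change 2.24 ± 0.26, adjusted p = 0.0109) and Camp, an antimicrobial peptide gene, from 199.5 to 421 (log2 change 1.08 ± 0.16, adjusted p = 0.0311), 2 being called when adjusted over the list alone. That list had an adjusted p of 0.0857, or 1.06e-04 without array 2.

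The apoptosis regulators were higher as a list (27 genes, 0 called, 2 when adjusted over the list alone, adjusted p = 0.0193; adjusted p = 0.0848 with an estimated correlation), and not without wild-type LSK array 3 (adjusted p = 0.151). Bcl2l11, which encodes the cell death protein Bim, read 227 and 1068 (adjusted p = 0.0609, and 1.62e-04 without array 2). The G2 and M phase list had 0 of 29 genes called, also when adjusted over the list alone (adjusted p = 0.0403; adjusted p = 0.108 with an estimated correlation), and did not pass without array 1, 3 or 5 (adjusted p = 0.111, 0.186 and 0.152). The cell cycle inhibitors had 0 of 17 genes called in either way (adjusted p = 0.0284; adjusted p = 0.456 with an estimated correlation), and did not pass without array 2 or 4 (adjusted p = 0.643 and 0.0688).

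Markers of other cells that a sort could hold did not pass as lists in LSK cells. The adjusted p was 0.665 for monocytes and macrophages, where Ccr2 fell, 0.288 for megakaryocytes, 0.429 for lymphoid progenitors, where Igll1 fell, 0.673 for mature B cells, 0.0575 for T and NK cells and 0.948 for stroma and endothelium. Among processes it was 0.925 for FoxO targets, 0.721 for S phase, 0.184 for p53 targets, 0.852 for interferon response, 0.665 for immediate-early and dissociation genes, 0.817 for glycolysis, 0.925 for oxidative phosphorylation and 0.126 for hypoxia response. It was 0.721 for autophagy and lysosome, 0.721 for ribosomal proteins, 0.378 for cholesterol synthesis, 0.925 for the unfolded protein response, 0.687 for insulin and PI3K signalling and 0.682 for the Wnt pathway. The median had the sign opposite to the mean for FoxO targets, stromal and endothelial genes, interferon response, oxidative phosphorylation and the unfolded protein response. Without array 2 the FoxO targets were lower (adjusted p = 0.0156; 0.158 with an estimated correlation).

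The LSK calls lean on the spread shared by all 12 arrays. With limma fitted to the LSK arrays alone, 0 genes were called, and 892 had an unadjusted p under 0.05. Without any 1 of arrays 4 to 12 the count lay between 9 and 23. Of the 16 genes named for the largest changes, 8 passed without any 1 array, namely Mir1931, Xcl1, Sik1, Mcpt8, B3galt6, Ccr2, Foxo4 and Gdpd3, while Ang and Trim12a did not pass without array 2 (adjusted p = 0.0505 and 0.0599).

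In FoxO-deficient myeloid progenitors, the immediate-early genes, which growth factors, stress or tissue dissociation switch on within minutes, were far lower than in wild-type myeloid progenitors. The transcription factor genes Fos, Jun and Egr1 fell from 3019 to 121 (log2 change -4.64 ± 0.18, adjusted p = 1.34e-06), from 1851 to 74.3 (log2 change -4.64 ± 0.24, adjusted p = 4.93e-06) and from 3309.7 to 228 (log2 change -3.86 ± 0.12, adjusted p = 4.57e-07). Zfp36, which destabilises inflammatory messenger RNAs, fell from 511 to 33.0 (log2 change -3.95 ± 0.14, adjusted p = 8.72e-07). Of 30 measured genes of this list, 26 fell and 1, Myc, rose from 163 to 328 (log2 change 1.01 ± 0.18, adjusted p = 0.0191), with 28 called when adjusted over the list alone. The list had a median log2 change of -3.01 (camera, adjusted p = 1.60e-61; adjusted p = 1.85e-06 with an estimated correlation). In LSK cells Fos read 4167 in wild-type and 4291 in deficient cells, and Egr1 4452 and 4459.

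**Figure D3:**
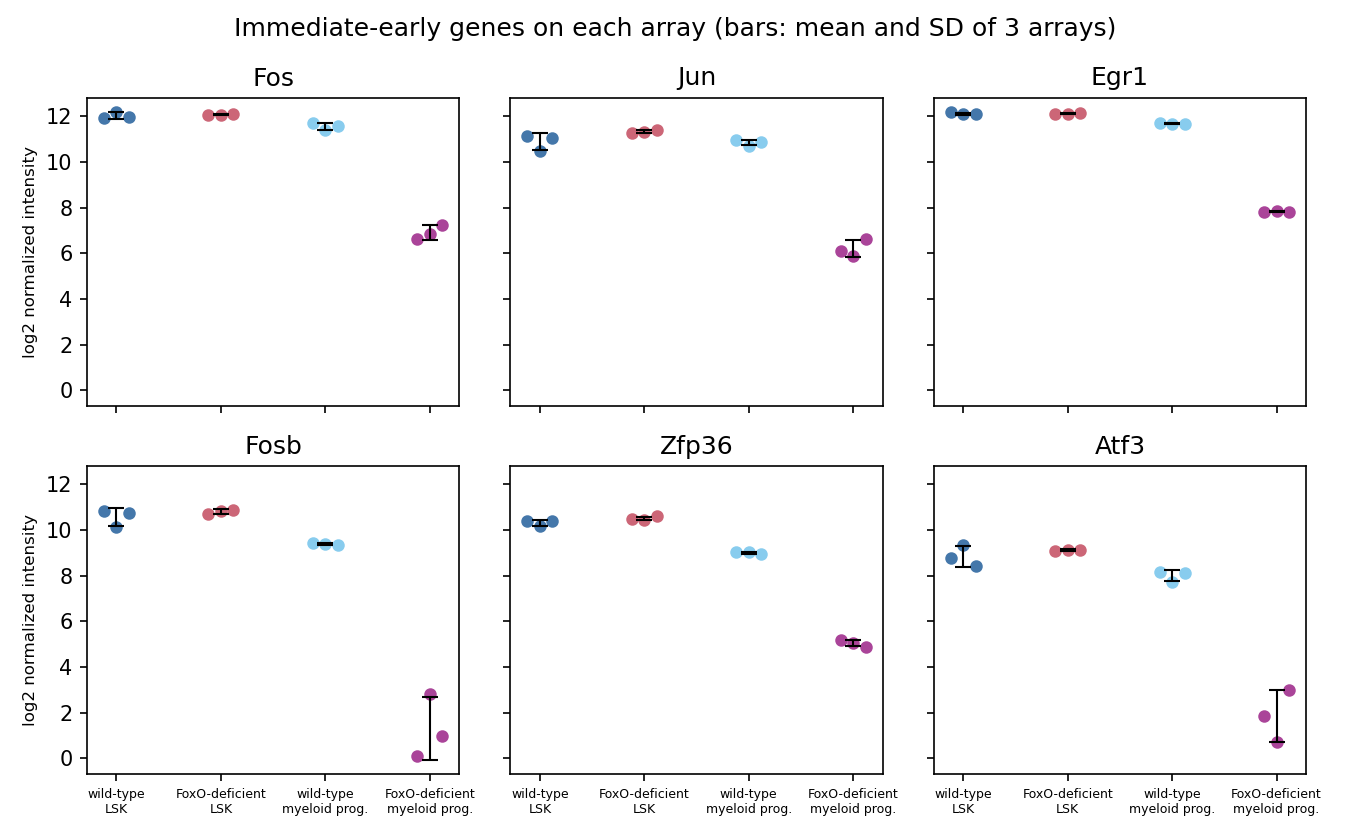
Log2 normalized intensity of Fos, Jun, Egr1, Fosb, Zfp36 and Atf3 on each array by group, with bars for the mean and SD of 3 arrays. For each of these genes the 3 arrays of FoxO-deficient myeloid progenitors lie below the arrays of all other groups.

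Among the other named genes, Fosb fell at least 71.6-fold, the stress-induced transcription factor gene Atf3 at least 27.6-fold, the nuclear receptor genes Nr4a3 and Nr4a1 at least 15.4-fold and at least 8.04-fold, Egr3 at least 15.4-fold, the chemokine gene Ccl3 at least 48.6-fold and Ptgs2, the inducible cyclooxygenase, at least 15.0-fold, each to a level not above background. The neutrophil chemokine gene Cxcl2 fell from 701 to 6.03, not above background on 2 of 3 arrays. The largest rises, each from a level not above background, were Trim30d (at least 8.51-fold), the immunoglobulin segment Igkv8-30 (at least 4.61-fold), Jchain, which links immunoglobulin polymers (at least 4.17-fold), Trim12a (at least 4.04-fold), the small GTPase gene Rab23 (at least 1.88-fold), Tpd52l1 (at least 1.32-fold) and the zinc finger gene Zfp14 (at least 1.10-fold). The second probe set of Trim12a moved less here too, by a log2 change of 0.90. Txlnb was called at 1.02 and 6.91, near background, with a second probe set of opposite sign. The adjusted p of these 16 genes lay between 1.68e-06 and 0.0390. In all, 253 genes were called, 104 higher and 149 lower. The balance turned with array weights (752 higher and 478 lower), an offset of 32 (284 and 220) and the 60th percentile filter (215 and 192). It also turned in a fit of only the groups compared (363 and 281), and leaned lower in the other alternatives that left out no array.

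Erythroid genes were lower in FoxO-deficient myeloid progenitors (median log2 change -0.62 over 26 genes, adjusted p = 9.48e-08; adjusted p = 0.00545 with an estimated correlation). Of these 1 was called, over all genes and over the list alone: Tspan33, which fell from 746 to 297 (log2 change -1.33 ± 0.22, adjusted p = 0.0158). Epor, the erythropoietin receptor, read 62.3 and 34.6 and Rhag, of the red cell membrane, 118 and 62.0 (adjusted p = 0.219 and 0.126). Granulocyte-monocyte progenitor genes were higher (26 genes, adjusted p = 8.31e-04; adjusted p = 0.0249 with an estimated correlation), with 1 called over all genes and over the list alone, Gfi1, which rose from 248 to 444 (log2 change 0.84 ± 0.17, adjusted p = 0.0359). Late neutrophil granule genes were higher (16 genes, adjusted p = 8.31e-04; adjusted p = 0.124 with an estimated correlation). Camp rose from 93.9 to 164 (log2 change 0.80 ± 0.16, adjusted p = 0.0401), S100a9 read 1728 and 2504 (adjusted p = 0.0755), and 5 were called when adjusted over the list alone. Interferon response genes were higher (32 genes, adjusted p = 0.00610; adjusted p = 0.0503 with an estimated correlation), with Oas2 called over all genes and over the list alone at 2.37 and 8.05, near background, and the GTPase gene Ifi47 at 174 and 336 (adjusted p = 0.150).

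Of 41 FoxO targets, 5 fell and 0 rose, with 9 called when adjusted over the list alone. The transcription factor gene Klf6 fell from 1389.5 to 229.8 (log2 change -2.60 ± 0.23, adjusted p = 2.44e-04), the pseudokinase gene Trib1 from 96.9 to 3.16 and Klf2 from 35.7 to 5.33, both not above background on 2 of 3 arrays, the cell cycle inhibitor gene Cdkn1a from 113 to 33.1 (log2 change -1.77 ± 0.30, adjusted p = 0.0157) and Ddit4, an inhibitor of mTOR signalling, from 1580.0 to 379.5 (log2 change -2.06 ± 0.42, adjusted p = 0.0408). The list was lower (adjusted p = 0.00461; adjusted p = 0.290 with an estimated correlation), and Klf2 and Klf6 also stand on the immediate-early list. Of 17 cell cycle inhibitors, Btg2 fell from 132 to 14.6, Tob1 from 322 to 149.7 and Cdkn1a as above, and Rbl1, of the retinoblastoma family, rose from 488 to 763, with 1 of 2 other probe sets of opposite sign. The list was lower, with 7 called when adjusted over the list alone (adjusted p = 0.00177; adjusted p = 0.441 with an estimated correlation), and Btg2 stands on the immediate-early list too.

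Other lists did not pass in myeloid progenitors, though some held called genes. The adjusted p was 0.919 for HSC genes, where Tek fell from 90.7 to 42.0 and Vldlr rose from 48.5 to 118, and 0.211 for eosinophil, basophil and mast cell genes, where the mast cell protease gene Cma1 rose at least 1.38-fold. It was 0.332 for monocytes and macrophages, where Cd14, a receptor for bacterial lipopolysaccharide, fell from 100.1 to 12.7, and 0.332 for megakaryocytes, where Thbs1 fell from 162 to 14.3. It was 0.175 for lymphoid progenitors, where Ebf1 fell at least 1.41-fold, 0.401 for mature B cells, where Jchain rose, 0.515 for T and NK cells and 0.840 for stroma and endothelium.

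Among processes in myeloid progenitors, the adjusted p was 0.332 for S phase, where the cyclin gene Ccne1 fell from 281 to 138, 0.785 for G2 and M phase, 0.840 for apoptosis regulators and 0.515 for p53 targets, where Pmaip1, a cell death gene on both of the latter lists, fell from 348 to 73.1. It was 0.534 for hypoxia response, where Bhlhe40 fell from 158 to 14.4 and Vegfa from 120.0 to 47.8, its other probe set being of opposite sign, and 0.122 for autophagy and lysosome, where the autophagy receptor gene Sqstm1 fell from 406 to 32.2. It was 0.931 for the unfolded protein response, where Atf3, Ddit3 (from 88.8 to 39.7) and Dnajb9 (from 448 to 282) fell, 0.411 for insulin and PI3K signalling, where the kinase gene Sgk1 fell from 739 to 363, and 0.919 for cholesterol synthesis, where Sc5d rose from 34.0 to 77.8. It was 0.840 for glycolysis, 0.145 for oxidative phosphorylation, 0.417 for ribosomal proteins and 0.515 for the Wnt pathway, where Myc rose. The median had the sign opposite to the mean for glutathione metabolism, HSC genes, p53 targets, hypoxia response and the unfolded protein response. Without array 2, oxidative phosphorylation and autophagy and lysosome were lower (adjusted p = 0.0221 and 0.0495; 0.462 and 0.106 with an estimated correlation).

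Without wild-type LSK array 2, whose values widen the spread estimated for many genes, 1196 genes were called in myeloid progenitors, 720 higher and 476 lower, with all 253 among them. The count was 130, 152, 163, 148 and 152 without array 7, 9, 10, 11 or 12.

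**Figure D4:**
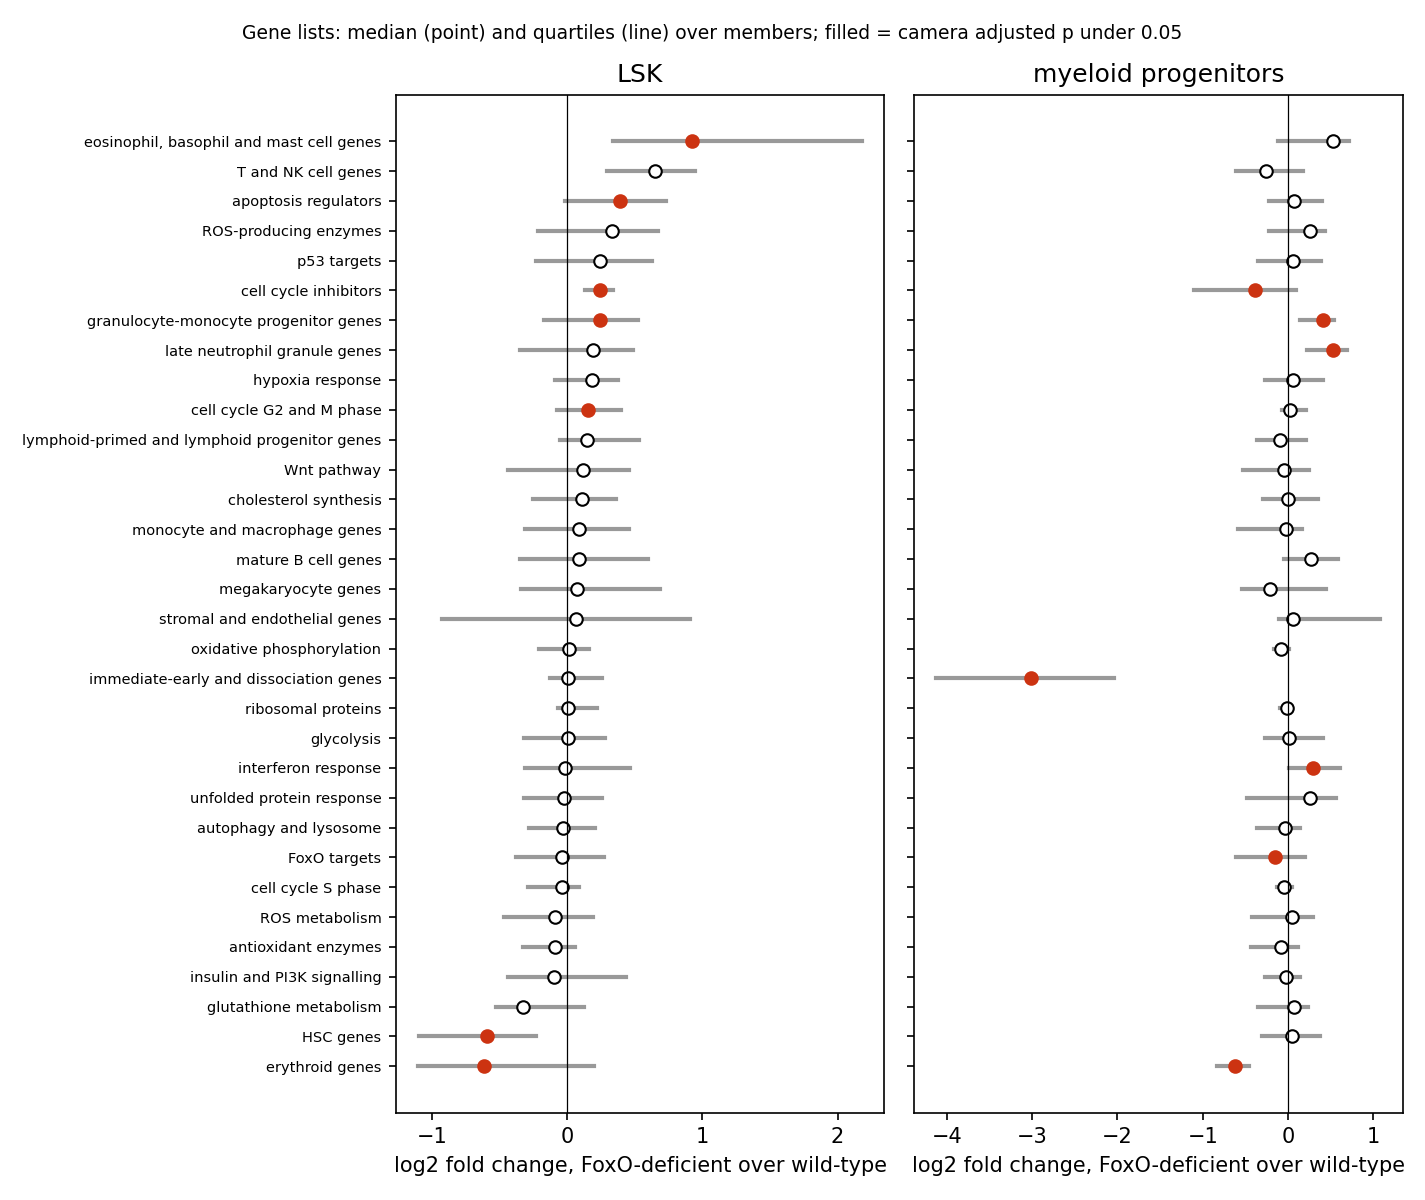
Median log2 fold change (points) and quartiles (lines) of FoxO-deficient over wild-type for the members of each gene list in LSK cells and in myeloid progenitors, with filled points where camera gave an adjusted p under 0.05. The immediate-early list has a median of -3.01 in myeloid progenitors and 0.01 in LSK cells, and the erythroid list has -0.62 and -0.62, or -0.61 and -0.27 without wild-type LSK array 2.

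Genes of ROS metabolism, the study's stated question, did not pass as a group in either cell type. The test looks for a shift of the whole list in a single direction. In LSK cells antioxidant and glutathione genes leaned down and ROS-producing enzymes up, so opposite changes could cancel in it. Of 90 measured genes, 1 was called in LSK cells: Gstm2, a glutathione S-transferase, fell from 36.5 to 15.8 (log2 change -1.21 ± 0.17, adjusted p = 0.0287). In myeloid progenitors 2 were called: Oxr1, an oxidation resistance gene, rose from 620.0 to 1048 (log2 change 0.76 ± 0.15, adjusted p = 0.0405), and Ptgs2 fell with the immediate-early genes. Adjusted over the list alone, 1 gene was called in LSK cells and 4 in myeloid progenitors. The list's adjusted p was 0.429 in LSK cells (median log2 change -0.09, or -0.02 without array 2) and 0.332 in myeloid progenitors, where the median was 0.04 and the mean -0.11, camera's direction being down. The difference between the cell types had an adjusted p of 0.916.

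By part, the antioxidant enzymes had an adjusted p of 0.188 in LSK cells and 0.153 in myeloid progenitors. Glutathione metabolism, with a median of -0.32 in LSK cells and 3 genes called when adjusted over the list alone, had 0.0973 and 0.678, and without array 2 the LSK median was -0.04 (adjusted p = 0.296). The ROS-producing enzymes, with a median of 0.33 in LSK cells, had 0.0973 and 0.971, and without array 2 that median was 0.14 (adjusted p = 0.417). In LSK cells this list passed in 5 of 27 alternatives, among them without array 6 (adjusted p = 0.0375). In myeloid progenitors its median of 0.26 and mean of -0.15 had opposite signs.

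Gsta4, a glutathione transferase of lipid peroxidation products, read 259 and 139.7 in LSK cells and 204 and 106 in myeloid progenitors (adjusted p = 0.194 and 0.0800). In LSK cells Sod3, the extracellular superoxide dismutase, read 7.64 and 0.991 (adjusted p = 0.122), and Srxn1, which restores oxidised peroxiredoxins, 210.2 and 385 (0.196). Epx, Pgd, Smox and Txnrd2 read 3.77 and 19.8, 1879 and 1173, 106 and 223, and 23.0 and 7.98, with adjusted p from 0.189 to 0.248. In myeloid progenitors Ncf4, part of the NADPH oxidase, read 143 and 252 (0.0666), and the peroxidase gene Prdx2 2091 and 1514 (0.106). Alox12, Gstm5 and Smox read 6.74 and 1.63, 643 and 448, and 26.5 and 13.3, with adjusted p from 0.111 to 0.159. Without array 2, 1 member was called in LSK cells, and in myeloid progenitors 4 were higher and 9 lower, with adjusted p = 0.592 and 0.396 for the list. With array 2 in the spread, simulated 2-fold changes of single genes were recovered in 19.2% of cases in LSK cells and 20.5% in myeloid progenitors (means of 100 draws).

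**Figure D5:**
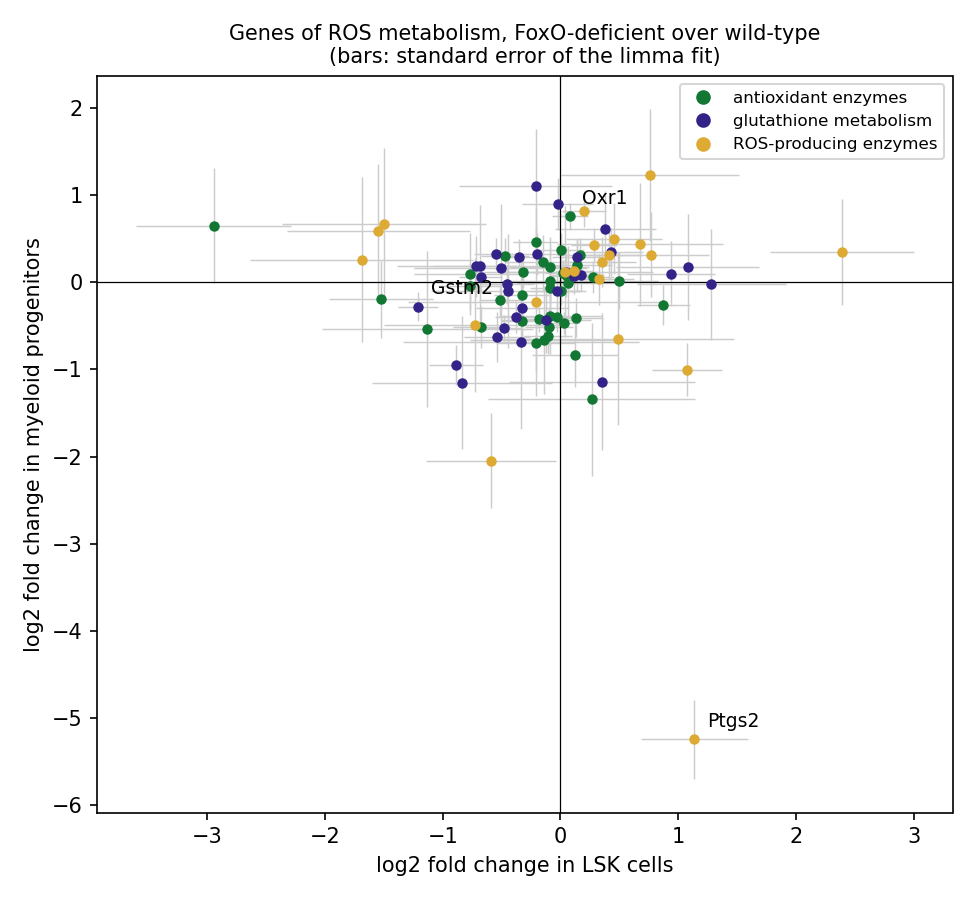
Log2 fold change of FoxO-deficient over wild-type in LSK cells (horizontal) against myeloid progenitors (vertical) for the genes of the 3 ROS lists, with standard errors of the fit. The called genes are labelled: Gstm2 at -1.21 in LSK cells, Oxr1 at 0.76 and Ptgs2 at -5.25 in myeloid progenitors, the last a fitted value to a level not above background.

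The FoxO effects in the 2 cell types shared few called genes. Arsk, B3galt6, Foxo4, Gdpd3 and Tek fell in both, and Camp, Cd244a, Mir1931 and Trim12a rose in both. In myeloid progenitors the other probe set of Arsk and 1 of 2 of B3galt6 had the opposite sign (1.04 and 1.29). Lmna and Ddx4 were called in opposite directions, 1 of 3 other Lmna probe sets having the opposite sign in myeloid progenitors, and these, with Cd244a, a receptor gene, were named after their values were seen. Independent sets of these sizes would share 0.129 genes raised in both and 0.217 lowered in both. Across genes the log2 changes had a Pearson r of 0.0569 and a Spearman rho of 0.0894, a description only, since genes are not independent replicates. Without array 2, 41 genes were shared in the same direction, against 3.75 higher and 2.05 lower expected, and without array 4, 5, 6, 7 or 12 between 4 and 5 were.

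Whether the FoxO effect differs between the cell types was tested directly. The immediate-early list differed most (adjusted p = 5.87e-54; adjusted p = 3.12e-06 with an estimated correlation), with 21 of its genes called. The other lists that differed were HSC genes (adjusted p = 9.50e-04; adjusted p = 0.217 with an estimated correlation), eosinophil, basophil and mast cell genes (adjusted p = 0.00225; adjusted p = 0.0750 with an estimated correlation; also lost with an offset of 32, 0.217) and cell cycle inhibitors (adjusted p = 4.66e-05; adjusted p = 0.217 with an estimated correlation). The adjusted p of the rest ran from 0.0642 to 0.971. Without array 2, erythroid genes, interferon response and oxidative phosphorylation also passed (adjusted p = 0.0184, 0.0307 and 0.0307), and none of these did with an estimated correlation. Largest among single genes were Fosb, Cxcl2, Ccl3, Nr4a3 and Atf3 on the lower side, with log2 differences from -8.30 to -6.40, and Txlnb, Cox8b, a cytochrome c oxidase subunit, Trim30d, Rab23 and Igkv8-30 on the higher side, with the other probe set of Txlnb and 1 of 2 of Rab23 of opposite sign. In all, 118 genes differed, 40 with the higher effect in myeloid progenitors and 78 with the lower, and 97 of them were also called in myeloid progenitors and 8 in LSK cells. The count was 467 without wild-type LSK array 2, 230 higher and 237 lower, and between 58 and 78 without any 1 of arrays 4 to 12.

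Wild-type myeloid progenitors were higher than wild-type LSK cells in erythroid, granulocyte-monocyte progenitor, eosinophil, basophil and mast cell genes and lower in genes of HSCs. Erythroid genes were higher (20 of 26 called higher and 1 lower, adjusted p = 3.36e-14), as were granulocyte-monocyte progenitor genes (20 of 26, adjusted p = 2.58e-14) and eosinophil, basophil and mast cell genes (9 of 15 higher and 1 lower, adjusted p = 5.56e-04). Car1 read 174 and 3345 in LSK cells and myeloid progenitors (log2 change 4.26 ± 0.14), the erythroid membrane gene Ermap 58.4 and 1744 (4.90 ± 0.21), Elane 95.5 and 1689 (4.15 ± 0.24) and Hdc 9.24 and 227 (4.62 ± 0.33). HSC genes were lower (27 of 35, adjusted p = 1.58e-20), with the transcription factor genes Mecom at 2536 and 151 (-4.07 ± 0.16) and Hlf at 1229 and 69.0 (-4.15 ± 0.27). In all, 2942 genes were called, 1367 higher and 1575 lower. Without array 2, 4711 were called, 2482 higher and 2229 lower, with 2763 in both sets. Median centring of the arrays gave 2177 higher and 1210 lower.

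Lists of respiration and proliferation were higher in myeloid progenitors: oxidative phosphorylation (22 of 50, adjusted p = 1.19e-08), G2 and M phase (13 of 29, adjusted p = 2.50e-07) and S phase (9 of 29, adjusted p = 3.86e-05). Ccne2, the cyclin E2 gene, read 37.1 and 113 (1.61 ± 0.25) and Cycs, of cytochrome c, 709.7 and 1595 (1.17 ± 0.17). Lower in myeloid progenitors were interferon response (15 of 32, adjusted p = 5.41e-05), stromal and endothelial genes (6 of 17, adjusted p = 0.00943) and immediate-early genes (9 of 30, adjusted p = 4.84e-04). So were mature B cell genes (7 of 15, adjusted p = 2.40e-04; adjusted p = 0.0511 with an estimated correlation), late neutrophil granule genes (7 of 16 lower and 1 higher, adjusted p = 0.00721; adjusted p = 0.133 with an estimated correlation) and FoxO targets (13 of 41 lower and 1 higher, adjusted p = 5.78e-04; adjusted p = 0.130 with an estimated correlation), among them Pdk4, a brake on glucose oxidation, at 212 and 4.40, the latter not above background on 2 of 3 arrays. The lists of this comparison for which no other p is given also passed with an estimated correlation. Adjusted over the list alone, the counts called were 30 for HSC genes, 23 for erythroid genes, 20 for granulocyte-monocyte progenitor genes and 27 for oxidative phosphorylation. The adjusted p of the remaining lists ran from 0.117 to 0.974, with 0.682 for ROS metabolism. Without array 2 insulin and PI3K signalling was lower (adjusted p = 0.0256; 0.0957 with an estimated correlation).

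Among single genes in myeloid progenitors against LSK cells, the largest rises were Ltbp1, which binds latent TGF-beta (4.18 and 247), Slc45a3 (at least 7.43-fold), the water channel gene Aqp1 (12.4 and 559), Asb17 (3.43 and 138) and Dmkn (at least 6.96-fold). The largest falls were the immunoglobulin genes Igkv8-30 (at least 87.3-fold), Jchain (at least 63.7-fold) and Igk (1092 and 12.4), the transporter gene Abcg3 (at least 14.1-fold) and Ccn3 (at least 12.0-fold), a matrix protein gene. The adjusted p of these 10 genes lay between 4.84e-07 and 7.11e-04.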

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

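The tests of RNA degradation, handling, a shared FoxO effect, carry-over of myeloid progenitors, the degraded array and variants under single probe sets were chosen after the results were seen, and those of strain segments and of other splits of the arrays before.

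The FoxO effect differed between the cell types in 118 genes, tested as the difference of the log2 changes. The largest differences in each direction were 4.31 ± 0.70 for Txlnb, 4.23 ± 0.66 for Cox8b, 3.93 ± 0.72 for Trim30d, 3.77 ± 0.37 for Rab23 and 3.69 ± 0.40 for Igkv8-30, then -8.30 ± 0.77 for Fosb, -7.87 ± 0.50 for Cxcl2, -6.95 ± 0.40 for Ccl3, -6.62 ± 0.77 for Nr4a3 and -6.40 ± 0.67 for Atf3. Each of these genes had a group at or near background, so these are fitted values and not bounds. Trim30d passed in 8 of the 23 alternatives that tested it and Txlnb in 10 of 22, while the 5 on the lower side passed in all. Among lists, the effect differed for HSC genes (adjusted p = 9.50e-04), eosinophil, basophil and mast cell genes (adjusted p = 0.00225), cell cycle inhibitors (adjusted p = 4.66e-05) and immediate-early and dissociation genes (adjusted p = 5.87e-54). With an estimated correlation only the last of these passed. Of 100 relabelings of genotype within each cell type, 2 gave as many genes, the real one included. This sets the count of 118 only against the spread between these arrays, which may be technical. A chance difference between pools of mice therefore cannot be excluded. Relabeling also removes the effects within each cell type, so it does not test their difference alone. The highest other count, 255, came from the LSK labels as deposited with the myeloid progenitor labels swapped as a whole, which tests the sum of the 2 effects in place of their difference and calls genes changed in a single cell type as well; the next highest was 67. For the count of 4 lists, 25 of 100 relabelings gave as many, with 9 as the highest, so chance cannot be excluded.

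The low immediate-early genes of FoxO-deficient myeloid progenitors were weighed first. Degraded RNA is argued against, since the highest Gapdh 3′ over 5′ ratio of these 3 arrays was 2.03, under the 2.37 of the other intact arrays. Their ratios, from 1.77 to 2.03, all lay below those of wild-type myeloid progenitors, from 2.07 to 2.30. Whether this difference goes with handling was not tested. A FoxO effect common to both cell types is argued against as well, since the list's median log2 change was 0.0084 in LSK cells, with an SD of 0.45 over its members, and -3.01 in myeloid progenitors. Handling that switched these genes on in the other groups stays open: the 5 heat shock members had a median log2 change of -1.07, with Hspa1a, Hspa1b and Dnajb1 lower and Hspa8 and Hsp90aa1 near 0, and the labels do not say which groups were handled together, so handling and genotype cannot be told apart. A FoxO effect in myeloid progenitors may equally be the source and was not tested apart from handling. Nor can it be told apart from an effect of the Mx-Cre transgene, which only the deficient groups carried.

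The higher basophil and mast cell genes and lower HSC genes of FoxO-deficient LSK cells were weighed next. The degraded wild-type array is argued against as the whole cause, since without it the lists passed at adjusted p = 5.65e-09 and 1.28e-04, but the HSC median shrank from -0.59 to -0.33, so part of the HSC effect rests on that array, and with an estimated correlation the HSC list did not pass with or without it (adjusted p = 0.108 and 0.135). Carry-over of the whole myeloid progenitor mixture, erythroid progenitors included, into the sort is argued against too. At the share of 9.16% that basophil and mast cell genes need, 12 of 15 erythroid genes lay below the level expected. The median log2 of observed over expected for the 15 was -1.46, with Car1 at 94.2 against 392. With the degraded array 2 in the wild-type level that test has a narrow margin (upper quartile -0.50, just at the bound set for it, Hba-a2 above its expected level, and shares of the 7 genes from 0.60% to 68.4%), and without it, at a share of 15.5% (6.54% to 64.2%), 13 of 14 genes lay below, with a median of -1.46, an upper quartile of -1.16 and Hba-a2 no longer among the genes used. The test used erythroid genes only, so it does not reach carry-over without erythroid progenitors. Carry-over of basophil, mast cell or granulocyte-monocyte progenitors alone, and a shift within the LSK gate, may each give this pattern and were not tested.

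The genes changed the same way in both cell types, 41 without array 2, were weighed last. Both genotypes carried the floxed genes, so segments of another strain stay open around the transgene or elsewhere in the pooled mice: 5 pairs of these genes lay within 20 genes of each other, among them Arsk and Mctp1, Cd244a and Cd48, and Mir1931 and Lta4h, against a median of 2 in random sets (permutation p = 0.0759, 40 genes placed). Sequence variants under single probe sets stay open too, since the other probe sets of 22 genes moved by a median of 0.44 of the change of the called one, between the values set for either outcome. A FoxO effect common to both cell types is the biological alternative. Foxo4 itself is among these genes, but it was a target of the deletion, so its fall does not bear on that alternative. Of 100 relabelings, 1, the real one, gave an overlap of 9 with all arrays, and the highest other was 2, which decides nothing, since only 1 other relabeling called enough genes in both cell types to reach 9.

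For counts within a cell type, 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 37 genes in LSK cells and the highest other 3, with 7 and 1 lists, and 1 of the 10 splits gave as many. In myeloid progenitors the values were 253 and 5 genes and 7 and 3 lists, and between the wild-type cell types 2942 and 3 genes and 13 and 10 lists, with 1 of the 10 splits as large in each.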

How the results depend on the processing

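The offset of 32, alone and without wild-type LSK array 2, and the estimated correlation without that array were chosen after the data were seen, and the other alternatives before. No paired analysis was run, because the array numbers are not shared between groups and so show no pairing. They do not tell whether both cell types were sorted from the same pools of mice. Counts are given in the order FoxO effect in LSK cells, in myeloid progenitors, their difference, cell types and overlap, with main values of 37, 253, 118, 2942 and 9. Leaving out 1 array gave 9 and 128, 130 and 1196, 58 and 467, 2026 and 4711, and 4 and 41 as lowest and highest, the highest without wild-type LSK array 2 in each.

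The values as deposited gave 8, 113, 48, 1832, 4, and moved the median of all genes by 0.27 in LSK cells, 0.14 in myeloid progenitors and 0.11 between cell types. The split was 5 higher and 3 lower in LSK cells, and 6 higher and 42 lower for the difference. Median centring gave 22 in LSK cells and 72 for the difference (17 higher and 55 lower), and moved the median of all genes between cell types by 0.17. No filter gave 16, 75 for the difference and an overlap of 5, and the 60th percentile filter 93, 407, 185 and an overlap of 20. Every probe set gave 464, 187 and 4619 for the middle 3, where more features are tested. A fit of only the groups compared, with fewer arrays, gave 0, 644, 1100 between cell types and an overlap of 0. Array weights gave 148, 1230, 440 and an overlap of 48. The offset of 32 gave 169, 504, 212 and an overlap of 38, and without array 2 685, 1902, 1038, 5417, 169. The difference, mostly lower with all arrays, was then 610 higher and 428 lower, and 230 higher and 237 lower without array 2 alone. Except where said, the cause was not tested. The other alternatives stayed within 1.5 times the main count.

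The ROS metabolism list did not pass in LSK cells or myeloid progenitors under any of 27 alternatives (adjusted p 0.0972 to 0.770 and 0.191 to 0.619, down in all). Its direction for the difference turned with fry (0.682), with the mean of probe sets (0.852) and without array 4 or 7 (0.965 and 0.936, in a range of 0.805 to 0.966 over single arrays left out). The ROS-producing list turned up in myeloid progenitors, never passing, with no filter (0.852), the 60th percentile filter (0.948), the mean of probe sets (0.530), only the groups compared (0.479), array weights (0.713), the offset of 32 (0.740, and 0.635 without array 2), the estimated correlation without array 2 (0.635) and leaving out 1 of 8 single arrays (0.653 to 0.960). Under the mean of probe sets the log2 change, not called in the main setting, was -0.18 for Aurka in LSK cells and -0.33 for Anxa1 in myeloid progenitors, both positive otherwise. In LSK cells the ROS-producing list passed in 5 of 27 alternatives (0.00166 to 0.439 over all).

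With an estimated correlation, the lists that kept their calls for FoxO deficiency within a cell type were the eosinophil, basophil and mast cell genes in LSK cells and the immediate-early, erythroid and granulocyte-monocyte progenitor genes in myeloid progenitors. Without array 2 as well, those calls stood, granulocyte-monocyte progenitor genes in LSK cells (0.0243) and late neutrophil granule genes, cell cycle inhibitors and interferon response in myeloid progenitors (0.0190, 0.0474 and 0.0358) joined them, as did late neutrophil granule genes in LSK cells (0.0243). Between cell types, stromal and endothelial genes and late neutrophil granule genes lost their calls there (0.0957 and 0.0887), and mature B cell genes and FoxO targets kept theirs (0.0224 and 0.0129). fry, which tests whether a list's genes move one way on balance and does not compare it with other genes, ended 1 call in LSK cells, of the cell cycle inhibitors (0.216), and called glutathione metabolism (0.0148), ROS-producing enzymes (0.0260), hypoxia response (0.0148) and T and NK cell genes (0.0331) there. In myeloid progenitors it newly called eosinophil, basophil and mast cell genes (0.0236), lymphoid progenitor genes (0.0168), hypoxia response (0.0221) and autophagy and lysosome (4.25e-04), and it also added calls for the difference and between cell types. In LSK cells the calls of G2 and M phase and of cell cycle inhibitors were also lost with the mean of probe sets and with only the groups compared, the former with the 60th percentile filter, and the latter with the values as deposited, with array weights and with the offset of 32 without array 2. The difference for eosinophil, basophil and mast cell genes was lost with the offset of 32 (0.217, and 0.170 without array 2), and the antioxidant list was called in myeloid progenitors with that offset without array 2 (0.0499). Of 16 genes with the largest changes, 0 in LSK cells and 10 in myeloid progenitors passed in every alternative, and all kept their sign. Between cell types 10 of 10 passed. For the difference of the effects 5 of 10 passed in every alternative, all on the lower side, and all 10 kept their sign. Signal near background limits the folds of dim genes.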

Other observations

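No test was run for this part beyond the fits over all genes, and its genes were chosen after their values were seen. Some immunoglobulin transcripts were abundant in LSK cells of both genotypes and near background in wild-type myeloid progenitors, though Igk-V21 read 7.65 and 429 in the LSK groups. Igkv8-30 read 875 in wild-type and 1113 in deficient LSK cells, and 2.82 and 46.2 in the myeloid progenitor groups. Jchain read 639 and 1200.1, then 3.34 and 41.8. Ighm, the IgM heavy chain, read 69.2 and 458 in LSK cells (adjusted p = 0.159, and 2.93e-04 without wild-type LSK array 2), though only 2 of 8 other probe sets paired with it had the same sign.

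Xist, of the inactive X chromosome, was high and Y-linked genes were low on all arrays. The probe sets of Xist read between 958 and 2818, and those of the Y-linked genes Eif2s3y, Kdm5d and Uty at most 10.5, 8.42 and 6.27.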
